A study of Mus musculus with 6 samples.

How the data were processed

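Splenic CD11b+Gr-1high cells of Mus musculus on an H-2b background were profiled in 3 groups of 2 arrays each: wild type without a tumor, IRF8 KO without a tumor, and wild type bearing an AT-3 tumor. Per the labels, the cells were purified by flow cytometry to above 97% in independent experiments, RNA had an integrity number above 7, and biotin-labelled cRNA was hybridized. GenomeStudio is named per the submitters' processing notes. The labels do not say which experiment or how many animals each array stands for.

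The deposited table of unnormalized values holds 1 signal intensity per probe and array on a linear scale, per the file headers. Each intensity has a deposited detection p-value beside it, per the file headers, which sets the probe against negative controls on the same array. The series matrix holds 1 log2 value per probe and array as deposited by the authors, and the labels record no step behind it. Its scale and centring were found by comparison: it equals the quantile-normalized log2 of the intensities with no background correction, and its array medians were all 6.91 or 6.92. It was used as an alternative, which repeats the one without background correction. Counts of alternatives and of scalings therefore include the same values again.

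Gene names came from the platform annotation and were updated through Entrez identifiers for 34807 probes and through accessions for 11, and 67 kept the platform's symbol. In all, 34885 probes had 1 symbol, 18 had several and 10378 had none in the annotation used. Probes with several symbols or none were tested but not named.

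Intensities were background-corrected with normexp using the detection p-values, given an offset of 16, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1 under R 4.3.3. Probes with a detection p-value under 0.05 on at least 2 of 6 arrays were kept (17631 probes). The brightest probe stood for a gene, which left 12492 features, 9548 named genes and 2944 unnamed probes, all called genes here. Of 3521 genes with several probes, 28, 19 and 2 had probes called in both directions in KO against wild type, AT-3 against wild type and AT-3 against KO, and 1099, 1175 and 484 had both called and uncalled probes. Ltf and Lyz2, where the choice of probe matters, are described with the other observations.

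One mean per group was fitted by lmFit to the 6 arrays, with 3 residual degrees of freedom, and moderated by eBayes (4.29 prior degrees of freedom). Comparisons were KO minus wild type, AT-3 minus wild type and AT-3 minus KO, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The median SE of a log2 difference was 0.256. Arrays carry no counts, and their number limits the precision. No split of 2 against 2 arrays can give an exact p below the threshold, so no permutation test of single genes was run. A fold is given as a bound where the dimmer group was detected on neither array, for 579, 732 and 259 of the called genes.

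The gene lists, 29 in all, were fixed before the data were examined, as were the comparisons, the test, the rule for naming genes and all alternatives except those named as added later. They were tested with camera in limma with a preset correlation of 0.01, with camera and an estimated correlation, and with fry. Fry's directional p tests whether a list's genes move 1 way on balance and its mixed p whether they change in either direction, and neither sets the list against other genes. Lists share genes, so their results are not independent.

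Genes were named by rule: per comparison, the 10 with the largest rise and the 10 with the largest fall among named genes past the threshold whose arrays did not overlap; per list, up to the 2 that rose and the 2 that fell most; for both comparisons with wild type, the 5 with the largest smaller change in each shared direction and up to 5 called in opposite directions; and Irf8. Predicted and clone-named genes were left out, and list members were left out where room was short. Genes named beyond the rule are said to have been chosen after their values were seen.

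Because both comparisons use the same wild-type arrays, unchanged groups were simulated 100 times together with a simulated control that both shared. Alternatives were no background correction, normexp with an offset of 50 and no detection p-values, the authors' log2 values, the median of detected probes set equal, no filter, detection under 0.01 on all arrays, averaged probes, every probe on its own, a fit of only the arrays compared, eBayes with a trend and robust prior, a stricter threshold, a fit with the replicate number as a block, and leaving out each array in turn. When 1 array of a group is left, it is assumed to vary like the other groups. The median of all probes set equal and no scaling between arrays were added after the brightness of the AT-3 arrays was seen. The closing part gives their effects.

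The fit and the calls were tested on simulated log2 values for KO against wild type over 12492 genes. In each of 10 runs, 200 genes were changed. Background correction, scaling, the filter and the choice of probe were not part of this test. The fit recovered 21.2% of genes changed by 1 on the log2 scale and 96.8% of those changed by 2. Of the calls, 5.75% fell on unchanged genes. In the data 31.9% of genes were called in this comparison, a far larger share than was changed here, so these rates may not carry over. Camera with the preset correlation called a shifted gene set in 10 of 10 runs and an unshifted one in 0, at an unadjusted p under 0.05. Genes were drawn independently, whereas the estimated correlation of the S phase list was 0.944. These runs therefore do not test the calls of correlated lists. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3.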

Results

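RNA from CD11b+Gr-1high cells, a splenic fraction rich in neutrophils and their precursors, was measured on 6 Illumina bead arrays. Cells came from wild-type mice without a tumor, from IRF8 knockout (KO) mice and from mice bearing AT-3, a transplanted mammary carcinoma line, with 2 arrays per group. The cells had been sorted to above 97% purity, per the labels. Mean signal was 397 and 379 on the wild-type arrays, 407 and 421 on the KO arrays and 284 and 265 on the AT-3 arrays, and 31.0% to 38.4% of probes were detected per array. Across genes, log2 values correlated at 0.990 between the wild-type arrays, 0.970 between the KO arrays, 0.978 between the AT-3 arrays and 0.857 to 0.936 between arrays of different groups. Genes are not independent replicates, so these values carry no p. Differences below are log2 values with their standard error (SE) from limma, from 2 arrays per group, and adjusted p values are Benjamini-Hochberg values over all 12492 genes tested. With 2 arrays per group the precision is limited, and the p values measure the spread between these samples, since the labels do not say whether each array stands for 1 animal or a pool. Where a probe was detected on neither array of the dimmer group, the fold is given as "at least": the brighter group's mean against the higher of the lowest detected signal on the arrays and the probe's own value. A list's median "with the bounds" has such genes set at that fold. Folds and bounds hold for the main setting, and their size depends on the background taken off: without background correction, the called log2 changes of named genes were at a median of 0.706 of their main size, and the medians of called lists at 0.699.

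Irf8, which encodes an interferon regulatory factor needed for monocyte and dendritic cell development, was read first because it is the targeted gene. Its probe gave raw signals of 221.6 and 192.3 on the wild-type arrays, 127.1 and 156.7 on the KO arrays and 367.9 and 253.0 on the AT-3 arrays. After normalization these were 6.86 and 6.70, 4.85 and 5.34, and 8.82 and 8.09 on the log2 scale. Irf8 fell in KO cells (-1.69, SE 0.31, 3.22-fold lower, adjusted p = 0.0063) and rose in AT-3 cells (1.67, SE 0.31, 3.19-fold higher, adjusted p = 0.00651), so that AT-3 cells held 10.3-fold more than KO cells (3.36, SE 0.31, adjusted p = 0.00104). The KO signal was still above the negative controls, with detection p of 0.0289 and 0.00107. The position of the probe relative to the deleted part of the gene is unknown, so the reading checks the labels only in part. The KO call was lost without wild-type array 1 (-1.60, adjusted p = 0.0547) and without background correction (-0.635, adjusted p = 0.0511), over a range of 0.00304 to 0.0547 in all alternatives. The AT-3 call was lost without wild-type array 2 (1.57, adjusted p = 0.0600) and with no scaling between arrays (0.874, adjusted p = 0.0626), over a range of 0.00513 to 0.0626.

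**Figure D1:**
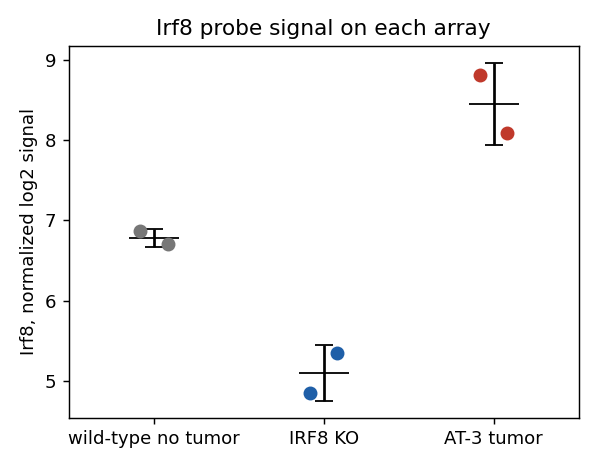
Irf8 on each of the 6 arrays, on the normalized log2 scale; points are arrays and lines are group means with the SD (n = 2). The KO arrays sit at 4.85 and 5.34, the wild-type arrays at 6.86 and 6.70 and the AT-3 arrays at 8.82 and 8.09.

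The comparison of KO with wild-type cells asked what loss of IRF8 did to this cell fraction. Mpo, which encodes myeloperoxidase of the primary granules, rose 174-fold (7.44, SE 0.93, adjusted p = 0.00158) and Elane, which encodes neutrophil elastase, rose 117-fold (6.88, SE 1.08, adjusted p = 0.00368). Both KO arrays lay above both wild-type arrays, but at different heights. Mpo rose by 5.78 without KO array 1 and by 9.08 without KO array 2, and Elane by 4.83 and 8.86. Olfm4, a marker of a neutrophil subset, rose 13.4-fold (3.75, SE 0.36), Orm1, an acute phase protein gene, 22.3-fold (4.48, SE 0.60), and Cybb, the NADPH oxidase core subunit, 6.30-fold (2.65, SE 0.39). Macrophage and interferon genes were among those with large falls. C1qb and C1qc, chains of complement C1q, fell by 5.90 (SE 0.28) and 5.88 (SE 0.27), Axl, a receptor for dying cells, by 5.02 (SE 0.25), Ifit3 by 6.21 (SE 0.61) and Oasl1 by 5.09 (SE 0.72).

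Of 11 measured primary granule genes, 8 rose, 1 fell and 2 did not pass, with the same counts when adjusted over the list alone. The exception was Ctsc, the protease that activates the granule serine proteases, which fell by 3.28 (SE 0.24). The list's median change was 3.92 (camera adjusted p = 0.000739 with a preset correlation), with adjusted p = 0.542 with an estimated correlation. The call was also lost with detection under 0.01 on all arrays (median 1.71, adjusted p = 0.230). Of 15 secondary granule genes, 9 rose and 6 did not pass (9 also when adjusted over the list alone), with a median of 1.42 (camera adjusted p = 0.000131, and adjusted p = 0.542 with an estimated correlation). Genes of mature neutrophils and tertiary granules went the other way: 3 rose, 14 fell and 7 did not pass of 24 (4 and 16 when adjusted over the list alone), with a median of -1.04 (camera adjusted p = 0.00433, and adjusted p = 0.588 with an estimated correlation). Stfa2l1 (-3.50, SE 0.25) and the chemokine gene Ccl6 (-3.38, SE 0.27) fell, while Wfdc21 rose by 2.04 (SE 0.29). Cxcr1, a chemokine receptor gene that is not in this list, fell too (-5.84, SE 1.09). The list's call was lost without KO array 1 (median -0.642, adjusted p = 0.0832, range over its alternatives 0.000315 to 0.588). Among 12 transcription factors of granulopoiesis, 4 rose and 4 fell, also when adjusted over the list alone. Cebpe and Gfi1, which act at the promyelocyte stage, rose 9.04-fold (3.18, SE 0.28) and 11-fold (3.46, SE 0.48), whereas Cebpb fell by 1.92 (SE 0.26) and Rara by 2.83 (SE 0.46). As a list they did not pass camera (median 0.58, adjusted p = 0.373) but passed fry, upward (adjusted p = 0.00414). Of 6 NADPH oxidase genes, 3 rose and 1 fell (4 and 1 when adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.123).

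Cell cycle genes rose together in KO cells. Of 22 G2/M genes, 18 rose and 4 did not pass (19 when adjusted over the list alone), with a median of 3.74 (camera adjusted p = 1.16e-10, and adjusted p = 0.542 with an estimated correlation). Of 24 S phase genes, 16 rose and 8 did not pass (19 when adjusted over the list alone), with a median of 2.30, or 2.15 with the bounds (camera adjusted p = 7.74e-07, and adjusted p = 0.588 with an estimated correlation). The S phase median was 1.13 without KO array 1. Top2a, the topoisomerase of dividing cells, rose 30.7-fold (4.94, SE 0.54, adjusted p = 0.00105), by 4.02 without KO array 1 and by 5.87 without KO array 2. Of 41 ribosomal protein genes, 6 rose and 35 did not pass, and 0 passed in limma when adjusted over the list alone, with 12 at an unadjusted p under 0.05. Their median was 0.43 (camera adjusted p = 0.00433, and adjusted p = 0.625 with an estimated correlation), a call lost without KO array 1 (median 0.249, adjusted p = 0.0720, range 7.31e-06 to 0.625). It was also lost with the median of detected probes set equal (median 0.0594, adjusted p = 0.204), with that of all probes (0.390, adjusted p = 0.0674) and with no scaling (0.433, adjusted p = 0.0602). Of 23 glycolysis and hypoxia genes, 7 rose and 8 fell (10 and 8 when adjusted over the list alone). That list had a median of 0.19, a mean of -0.12 and an upward test that did not pass (camera adjusted p = 0.857). The hexokinase gene Hk1 rose by 1.90 (SE 0.28) and the glucose transporter gene Slc2a1 fell by 2.87 (SE 0.38).

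Interferon-stimulated genes, which make antiviral proteins, fell in KO cells: 24 fell and 11 did not pass of 35 (27 when adjusted over the list alone), with a median of -2.29 (camera adjusted p = 1.92e-09, and adjusted p = 0.542 with an estimated correlation). Of 16 genes for MHC class II and antigen presentation, 10 fell and 6 did not pass (11 when adjusted over the list alone), with a median of -1.75 (camera adjusted p = 0.00011, and adjusted p = 0.542 with an estimated correlation). Lgmn, a lysosomal protease gene, fell by 4.46 (SE 0.24), and Cd86, a costimulatory ligand gene, fell by 3.49 (SE 0.37). Of 14 MHC class I and immunoproteasome genes, 5 fell and 9 did not pass (5 when adjusted over the list alone), among them Nlrc5, the class I transactivator (-2.63, SE 0.26). That list's median was -0.63 (camera adjusted p = 0.0161, and adjusted p = 0.588 with an estimated correlation). In the IRF and STAT family, 8 fell and 5 did not pass of 13 (10 when adjusted over the list alone), with a median of -1.02 (camera adjusted p = 0.000182, and adjusted p = 0.542 with an estimated correlation). Irf8, the targeted gene, is among the 8, and the list was not tested without it. Irf5 fell by 3.58 (SE 0.30). Stat3, singled out after its values were seen because the study's title names STAT, was -0.56 (adjusted p = 0.0718).

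Of 21 genes described as IRF8 targets or apoptosis genes, 1 rose and 12 fell (1 and 13 when adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.000185, and adjusted p = 0.542 with an estimated correlation). Mrc1, the mannose receptor gene, fell by 4.32 (SE 0.21) and Csf1r, the receptor for macrophage colony-stimulating factor, by 4.02 (SE 0.27), while Pml rose by 1.94 (SE 0.27). Of 22 STAT3 and STAT5 target genes, 4 rose and 9 fell (4 and 11 when adjusted over the list alone), with a median of -0.65, or -0.53 with the bounds (camera adjusted p = 0.0356, and adjusted p = 0.542 with an estimated correlation). Socs3 and Cish, feedback inhibitors of cytokine signaling, moved apart, with -4.19 (SE 0.54) and 2.77 (SE 0.37). That list's call was lost without KO array 1 (adjusted p = 0.106) and without KO array 2 (adjusted p = 0.0640), and with detection under 0.01 on all arrays (adjusted p = 0.226), over a range of 0.00442 to 0.542. Of 22 cytokine and chemokine genes, 1 rose and 13 fell, also when adjusted over the list alone, with a median of -1.48 (camera adjusted p = 6.55e-05, and adjusted p = 0.542 with an estimated correlation). That median was -2.33 without KO array 2. Of 25 receptor genes for growth factors and chemokines, 1 rose and 15 fell (2 and 15 when adjusted over the list alone), with a median of -1.10 (camera adjusted p = 5.18e-05, and adjusted p = 0.542 with an estimated correlation). Csf1 fell by 3.71 (SE 0.25), Ccl9 by 3.67 (SE 0.21) and Tnfrsf1b by 3.48 (SE 0.38).

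Of 21 suppressor effector genes, the products ascribed to myeloid-derived suppressor cells, 2 rose, 8 fell and 11 did not pass (3 and 8 when adjusted over the list alone). Cd274, which encodes the checkpoint ligand PD-L1, fell by 3.96 (SE 0.25). Wfdc17 fell by 6.53 (SE 0.56), by 7.24 without KO array 1 and by 5.77 without KO array 2. Ptges, a prostaglandin synthase gene, rose at least 2.65-fold (1.81, SE 0.30). Arg1, Nos2, S100a8 and S100a9, singled out after their values were seen, were at -0.35, -0.48, -0.04 and 0.33 and did not pass. The list's median was -0.48, or -0.35 with the bounds (camera adjusted p = 0.0495, and adjusted p = 0.542 with an estimated correlation), a call lost without wild-type array 1 (adjusted p = 0.0822), KO array 1 (0.138) or AT-3 array 2 (0.0661), over a range of 0.00991 to 0.542. It was also lost without background correction and with the authors' values (median -0.268, adjusted p = 0.0619), with averaged probes (-0.352, 0.0566) and with detection under 0.01 on all arrays (-0.793, 0.0509). Without KO array 2 the median was -0.766.

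Markers of other cell types were read as measured facts beside these groups. Of 22 monocyte and macrophage markers, 2 rose and 16 fell, also when adjusted over the list alone, with a median of -2.80 (camera adjusted p = 1.1e-07, and adjusted p = 0.542 with an estimated correlation). Ms4a6d fell 11.3-fold (-3.50, SE 0.27) and Ly6c1 rose by 1.70 (SE 0.22). Of 13 dendritic cell markers, 4 fell and 9 did not pass (4 when adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.115). Without KO array 2 that list passed (median -0.424, adjusted p = 0.0454). Batf3, a dendritic cell transcription factor gene, fell at least 4.89-fold (-2.55, SE 0.20), and Cd83 fell by 2.30 (SE 0.31). Of 14 B cell markers, 4 rose (4 when adjusted over the list alone), with a median of 0.12, or -0.00 with the bounds (camera adjusted p = 0.275). Of 10 T cell markers, 5 rose (6 when adjusted over the list alone), with a median of 0.93, or 0.46 with the bounds (camera adjusted p = 0.0376, and adjusted p = 0.588 with an estimated correlation). The T cell call was lost without wild-type array 1 (adjusted p = 0.0648) and without KO array 2 (median 0.352, adjusted p = 0.440), over a range of 0.00277 to 0.588. It was also lost without background correction and with the authors' values (median 0.338, adjusted p = 0.0619), with detection under 0.01 on all arrays (0.814, 0.324) and with no scaling (1.15, 0.0524). Of 5 NK cell markers, 1 rose (1 rose and 1 fell when adjusted over the list alone), with a median of -0.27, a mean of 0.37 and an upward test (camera adjusted p = 0.998). Of 17 erythroid markers, 2 rose and 2 fell, also when adjusted over the list alone, with a median of -0.10, or 0.00 with the bounds (camera adjusted p = 0.812). Hba-a1, an alpha-globin gene, fell by 4.79 (SE 0.28), and since hemoglobin genes have near-identical copies, its identity is uncertain.

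The smaller marker lists did not pass camera in KO cells. Of 8 megakaryocyte and platelet markers, 3 rose and 2 fell (3 and 4 when adjusted over the list alone), with a median of -0.29 (-0.09 with the bounds), a mean of 0.06 and a downward test (camera adjusted p = 0.994). Gp9 rose at least 2.91-fold and Vwf fell at least 2.53-fold. Of 3 eosinophil markers, 1 rose and 1 fell, also when adjusted over the list alone, with a median of 0.43 (0.25 with the bounds), a mean of 0.00 and a downward test (camera adjusted p = 0.958). Of 3 basophil and mast cell markers, 1 rose and 1 fell (1 and 2 when adjusted over the list alone), with a median of -0.91 (camera adjusted p = 0.346), though fry called them lower (adjusted p = 0.0481). Of 9 progenitor genes, 3 rose and 1 fell, also when adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.406).

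A list of 27 stress genes, which can rise during sorting and dissociation, was read for handling: 1 rose and 11 fell in KO cells, also when adjusted over the list alone. Its median was -0.53 (camera adjusted p = 0.00685, and adjusted p = 0.588 with an estimated correlation), a call lost without KO array 1 (adjusted p = 0.0931, range 0.000441 to 0.588) and with detection under 0.01 on all arrays (adjusted p = 0.110). Without KO array 2 the median was -1.02. In all, 3990 genes (31.9%) differed between KO and wild type, 1923 higher and 2067 lower, and 3034 of these by at least 2-fold. The arrays of both groups did not overlap for 69.2% of genes, against 33.3% by chance. The number called fell to 1561 without wild-type array 1 and to 1402 without wild-type array 2. Of the calls, 48.2% were higher with quantile scaling, 40.1% with the median of detected probes set equal, 61.3% with the median of all probes set equal and 64.6% with no scaling, where the median of all genes shifted by -0.17, 0.16 and 0.20.

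**Figure D2:**
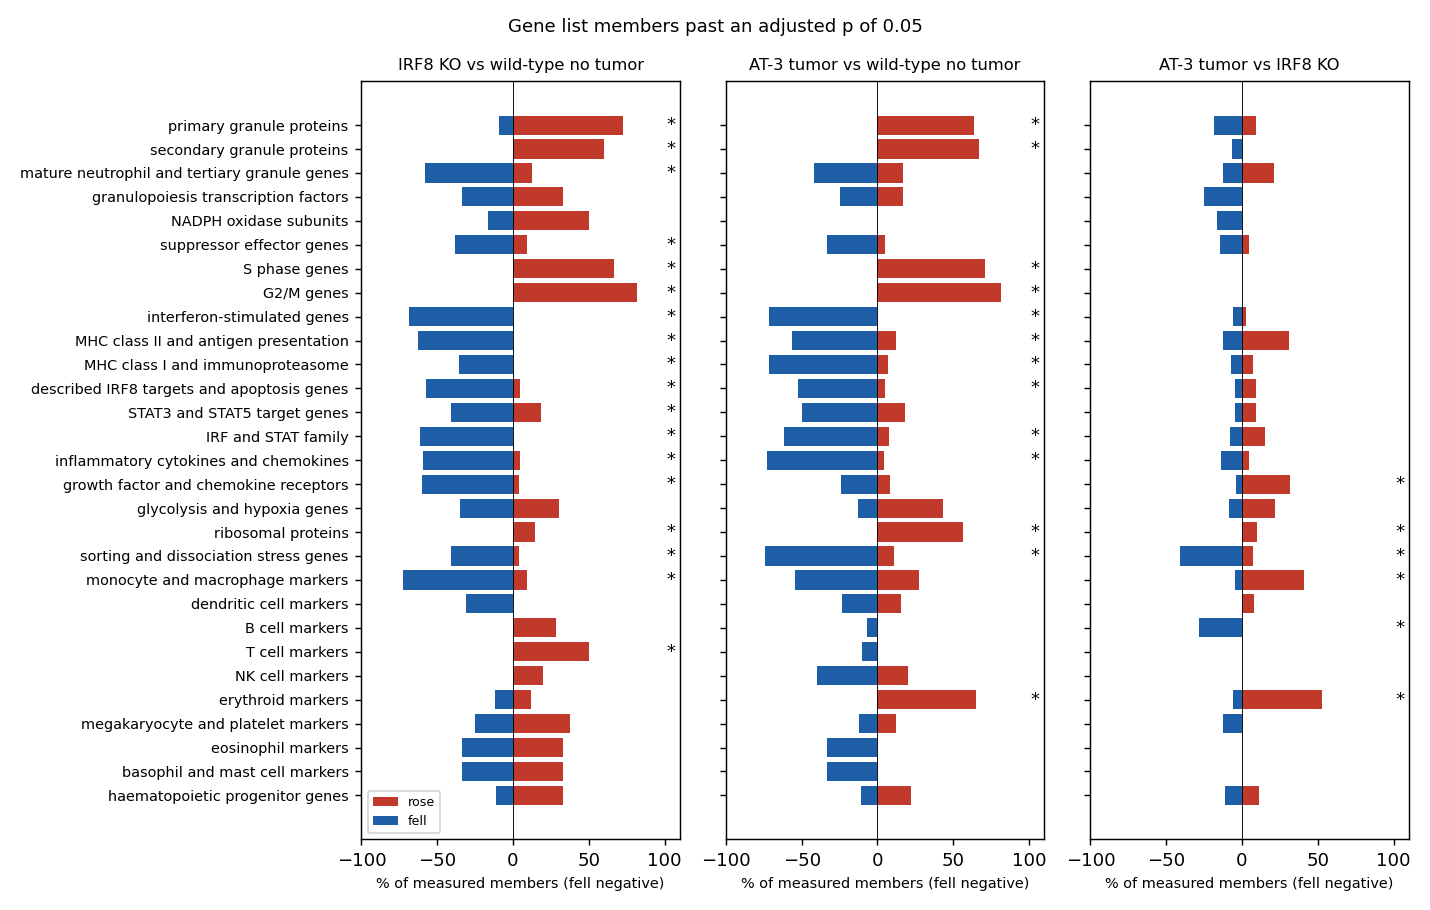
Percent of each list's measured genes that rose (red, positive) or fell (blue, negative) in each of the 3 comparisons; a star marks lists with a camera adjusted p under 0.05 with a preset correlation. Of G2/M genes, 18 of 22 rose in both comparisons with wild type, and of interferon-stimulated genes 24 and 25 of 35 fell.

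The comparison of AT-3 tumor with wild-type cells asked how cells of this fraction that expand in tumor-bearing mice differ from their counterparts in healthy spleen. Fn1, the fibronectin gene, rose 68.6-fold (6.10, SE 0.48, adjusted p = 0.000591), by 5.44 without wild-type array 2. F13a1, the coagulation factor XIII subunit gene of monocytes, rose 25.9-fold (4.70, SE 0.65), Stfa2, a neutrophil cysteine protease inhibitor gene, 26.1-fold (4.70, SE 0.43), and Ccr2, the chemokine receptor of inflammatory monocytes, 11.4-fold (3.51, SE 0.31). Slc4a1, the red cell anion exchanger gene, rose 52.1-fold (5.70, SE 0.53), by 4.85 without AT-3 array 1 and by 6.58 without AT-3 array 2. Among genes that fell, Ifit3 dropped by 6.43 (SE 0.61), which was -5.44 without AT-3 array 1 and -7.46 without AT-3 array 2. C1qc fell by 5.61 (SE 0.27), Vcam1, an adhesion molecule of splenic macrophages, by 5.51 (SE 0.41), Ccrl2 by 5.62 (SE 0.59), and Dusp2, an early response phosphatase gene, at least 37.9-fold (-5.71, SE 0.30), which was -3.42 without background correction.

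Granule and cell cycle genes rose here too. Of 11 primary granule genes, 7 rose and 4 did not pass (7 when adjusted over the list alone), with a median of 2.83, or 2.81 with the bounds (camera adjusted p = 0.000124, and adjusted p = 0.629 with an estimated correlation). Mpo rose 39.8-fold (5.32, SE 0.93, adjusted p = 0.00556), a call lost without background correction (3.32, adjusted p = 0.0502, range 0.000826 to 0.0502). Of 15 secondary granule genes, 10 rose and 5 did not pass (10 when adjusted over the list alone), with a median of 1.47 (camera adjusted p = 1.56e-05, and adjusted p = 0.629 with an estimated correlation). Itgb2l rose 6.60-fold (2.72, SE 0.25). Of 24 mature neutrophil genes, 4 rose and 10 fell (4 and 11 when adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.11). Of 12 granulopoiesis factors, 2 rose and 3 fell (3 and 4 when adjusted over the list alone), with a median of 0.19, a mean of -0.04 and an upward test (camera adjusted p = 0.919). Of 6 NADPH oxidase genes, 0 passed in limma, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median was 0.26 (camera adjusted p = 0.645). Cybb (0.92) was called without AT-3 array 2 (1.55, adjusted p = 0.0283) and with the median of detected probes set equal (1.36, adjusted p = 0.0111). Of 24 S phase genes, 17 rose (19 when adjusted over the list alone), with a median of 2.48, or 2.33 with the bounds (camera adjusted p = 5.63e-07, and adjusted p = 0.629 with an estimated correlation). Of 22 G2/M genes, 18 rose (18 rose and 1 fell when adjusted over the list alone), with a median of 3.52 (camera adjusted p = 7.87e-09, and adjusted p = 0.629 with an estimated correlation). Top2a rose 21.3-fold (4.42, SE 0.54) and Birc5, a mitotic survival gene, 23.2-fold (4.54, SE 0.43).

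Of 41 ribosomal protein genes, 23 rose and 18 did not pass (24 when adjusted over the list alone), with a median of 0.73 (camera adjusted p = 4.85e-07, and adjusted p = 0.629 with an estimated correlation). With no scaling between arrays that median was -0.00817, against -0.44 for all genes. Of 23 glycolysis and hypoxia genes, 10 rose and 3 fell, also when adjusted over the list alone, with a median of 0.18, or 0.10 with the bounds (camera adjusted p = 0.164). Without AT-3 array 1 that list passed (median 0.563, adjusted p = 0.0452). Pfkl, a phosphofructokinase gene, rose by 2.01 (SE 0.23).

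Interferon and inflammatory genes fell in AT-3 cells. Of 35 interferon-stimulated genes, 25 fell and 10 did not pass (27 when adjusted over the list alone), with a median of -1.90 (camera adjusted p = 7.96e-09, and adjusted p = 0.629 with an estimated correlation). Of 22 cytokine and chemokine genes, 1 rose and 16 fell (1 and 18 when adjusted over the list alone), with a median of -2.37 (camera adjusted p = 1.54e-06, and adjusted p = 0.629 with an estimated correlation). The member that rose was Ccl9 (2.18, SE 0.21), whereas Csf1 fell by 3.57 (SE 0.25) and the neutrophil chemokine gene Cxcl2 by 5.51 (SE 0.78). Cxcl2 fell by 4.74 without AT-3 array 1, by 6.36 without AT-3 array 2 and by 4.87 without wild-type array 2. Of 27 stress genes, which can rise during sorting and dissociation, 3 rose and 20 fell (3 and 21 when adjusted over the list alone), with a median of -2.23 (camera adjusted p = 5.63e-07, and adjusted p = 0.629 with an estimated correlation). A difference in handling between the groups therefore stays open for the fall of inflammatory genes. Of 13 IRF and STAT family genes, 1 rose, Irf8, and 8 fell (1 and 8 when adjusted over the list alone), with a median of -0.94 (camera adjusted p = 0.00787, and adjusted p = 0.629 with an estimated correlation). Stat4 fell by 1.91 (SE 0.27). Stat3, again singled out, was at -0.23 and did not pass.

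Of 21 described IRF8 targets and apoptosis genes, 1 rose and 11 fell (3 and 12 when adjusted over the list alone), with a median of -0.98, or -0.91 with the bounds (camera adjusted p = 0.00723, and adjusted p = 0.629 with an estimated correlation). The call was also lost with detection under 0.01 on all arrays (median -0.576, adjusted p = 0.0890). Mrc1 fell at least 17.8-fold (-4.68, SE 0.21), and Egr1, an early response factor gene, fell by 4.75 (SE 0.53). Of 22 STAT3 and STAT5 targets, 4 rose and 11 fell (5 and 12 when adjusted over the list alone), with a median of -0.72, or -0.66 with the bounds (camera adjusted p = 0.164, but fry adjusted p = 0.0472). Of 16 MHC class II and presentation genes, 2 rose and 9 fell (3 and 9 when adjusted over the list alone), with a median of -1.25, or -1.11 with the bounds (camera adjusted p = 0.0256, and adjusted p = 0.629 with an estimated correlation), a call also lost with detection under 0.01 on all arrays (median -0.802, adjusted p = 0.226). Cd74, the invariant chain gene, fell by 3.87 (SE 0.42), and Ifi30, a lysosomal thiol reductase gene, rose by 2.47 (SE 0.26). Of 14 MHC class I genes, 1 rose and 10 fell, also when adjusted over the list alone, with a median of -0.95 (camera adjusted p = 0.0068, and adjusted p = 0.629 with an estimated correlation). Nlrc5 fell by 1.97 (SE 0.26) and H2-Q7 by 1.95 (SE 0.34).

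Of 21 suppressor effector genes, 1 rose and 7 fell, also when adjusted over the list alone, with a median of -0.26, or -0.00 with the bounds (camera adjusted p = 0.164, but fry adjusted p = 0.0450). Cd274 fell by 4.59 (SE 0.25) and Slc7a11, the cystine transporter gene, at least 22.8-fold. Arg1, Nos2, S100a8 and S100a9, singled out as before, were at 0.34, 0.89, 0.19 and 0.44 and did not pass. Of 25 receptor genes, 2 rose and 6 fell, also when adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.157). Without wild-type array 2 or AT-3 array 2 that list passed (median -0.658 and -0.691, adjusted p = 0.0357 and 0.0410). Il3ra rose by 1.87 (SE 0.26) and Cxcr4 fell by 2.24 (SE 0.22).

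Among markers of other cell types, 11 of 17 erythroid genes rose and 6 did not pass (11 when adjusted over the list alone), with a median of 1.76, or 1.33 with the bounds (camera adjusted p = 1.99e-05, and adjusted p = 0.629 with an estimated correlation). The median was 0.861 without AT-3 array 1. With detection under 0.01 on all arrays the call was lost (camera adjusted p = 0.0552), though the median was still 1.76. Hba-a1 rose 6.37-fold (2.67, SE 0.28). Of 22 monocyte and macrophage markers, 6 rose and 12 fell (7 and 13 when adjusted over the list alone), with a median of -1.34 (camera adjusted p = 0.0772, but fry adjusted p = 0.0450). Ms4a6d rose 11.2-fold (3.48, SE 0.27) together with Fn1, F13a1 and Ccr2, while C1qc and Vcam1 fell. Of 13 dendritic cell markers, 2 rose and 3 fell (2 and 5 when adjusted over the list alone), with a median of -0.44, or -0.25 with the bounds (camera adjusted p = 0.205). Of 14 B cell markers, 1 fell (0 in limma when adjusted over the list alone, 3 at an unadjusted p under 0.05), with a median of -0.45, or -0.08 with the bounds (camera adjusted p = 0.164). Of 10 T cell markers, 1 fell, also when adjusted over the list alone, with a median of 0.29 (0.00 with the bounds), a mean of -0.00 and an upward test (camera adjusted p = 0.521). Of 5 NK cell markers, 1 rose and 2 fell, also when adjusted over the list alone, with a median of -0.05 (camera adjusted p = 0.834). Of 8 megakaryocyte markers, 1 rose and 1 fell (1 and 3 when adjusted over the list alone), with a median of -0.39, or -0.11 with the bounds (camera adjusted p = 0.403, but fry adjusted p = 0.0450). Of 3 eosinophil markers, 1 fell (1 when adjusted over the list alone), with a median of 0.03, a mean of -0.33 and a downward test (camera adjusted p = 0.566). Of 3 basophil markers, 1 fell (2 when adjusted over the list alone), with a median of -0.96 (camera adjusted p = 0.164, and 0.0302 without AT-3 array 2). Of 9 progenitor genes, 2 rose and 1 fell, also when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.330). Spink2 rose at least 3.77-fold.

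In all, 4360 genes (34.9%) differed between AT-3 and wild type, 2160 higher and 2200 lower, and 3186 of them by at least 2-fold. The arrays did not overlap for 71.9% of genes, against 33.3% by chance. The number called fell to 1576 without wild-type array 1, 1377 without wild-type array 2 and 2451 without AT-3 array 1. The AT-3 arrays were dimmer, and the split of calls depended on scaling: 49.5% were higher with quantile scaling, 66.6% with the median of detected probes set equal, 14.3% with the median of all probes set equal and 13.1% with no scaling. The median of all genes then shifted by 0.40, -0.38 and -0.44.

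**Figure D3:**
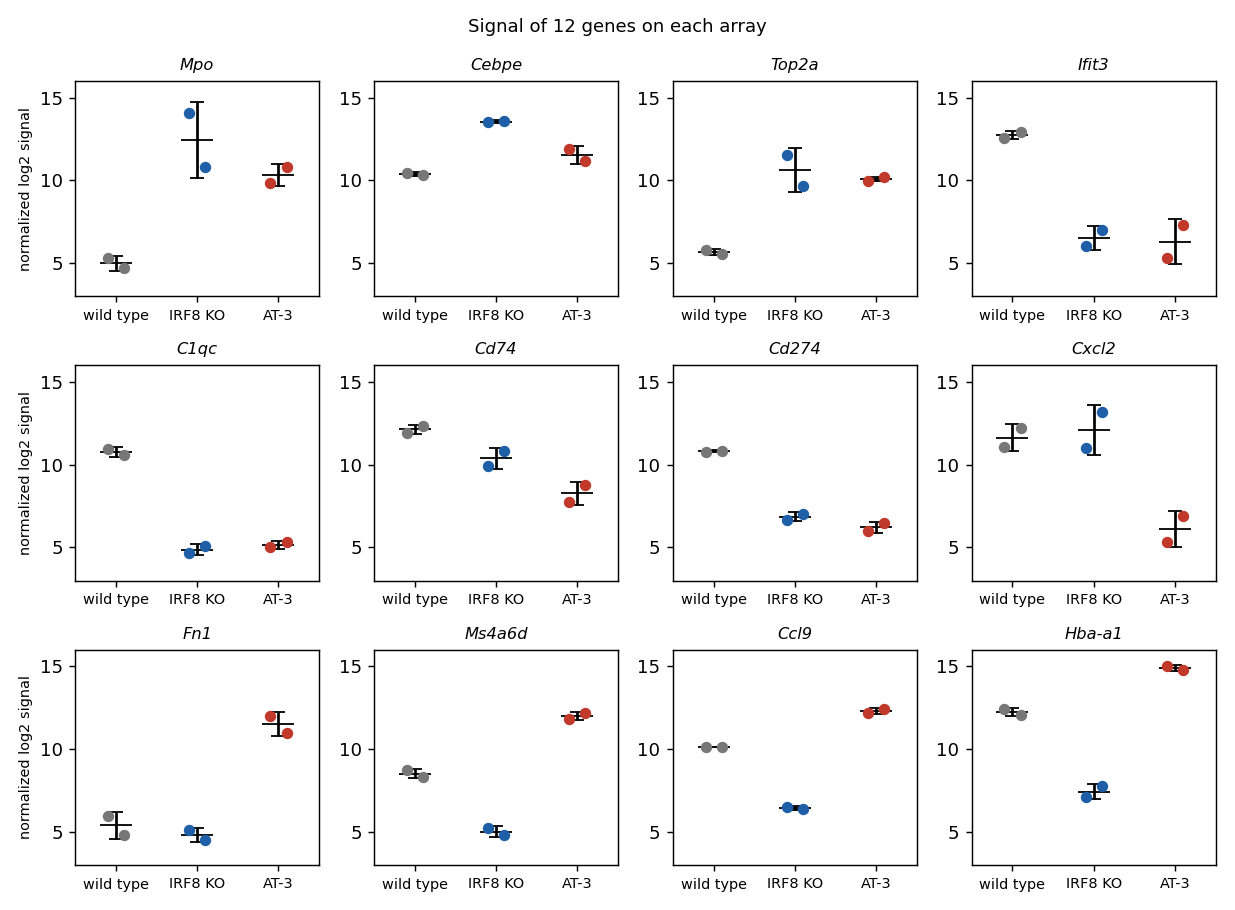
Normalized log2 level of 12 genes on each of the 6 arrays; points are arrays and lines are group means with the SD (n = 2). Mpo, Cebpe and Top2a are higher in KO than in wild-type cells, C1qc and Ifit3 are lower in both other groups, and Hba-a1, Ms4a6d and Ccl9 are lower in KO and higher in AT-3 cells.

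The series title concerns how suppressor cells develop, and both groups were compared with the same wild-type arrays to ask which changes they had in common. Of genes called in both, 1165 were higher in both, 1404 lower in both and 97 went in opposite directions. Independent lists would give 332.5, 364.0 and 696.1. Elane, Mpo, Ctsg, Top2a and Uhrf1 were among those higher in both, and Ifit3, C1qb, C1qc, Cass4 and Prr5l among those lower in both. Mpo and Elane in KO cells and Ifit3 in AT-3 cells depended in size on the array left out, as given above. Uhrf1, a DNA methylation cofactor gene, rose by 4.44 (SE 0.70) in KO cells, by 3.19 without KO array 1 and by 5.63 without KO array 2. In AT-3 cells Uhrf1 rose by 4.43 (SE 0.70). Ctsg, the cathepsin G gene, rose at least 32.0-fold in KO cells (5.48, SE 0.89), by 3.76 without KO array 1 and by 7.02 without KO array 2. In AT-3 cells it rose at least 18.3-fold (4.68, SE 0.89), a call lost without background correction (2.49, adjusted p = 0.0751, range 0.000781 to 0.0751). Elane rose by 5.84 (SE 1.08) in AT-3 cells, a call lost in the same way (3.79, adjusted p = 0.0529, range 0.000441 to 0.0529). Cass4 fell by 4.68 in KO and by 5.64 in AT-3 cells, where it was -5.00 without AT-3 array 1. Prr5l fell by 5.56 in KO and by 4.63 in AT-3 cells, where it was -3.49 without AT-3 array 1 and -5.92 without AT-3 array 2. Hba-a1, Hbb-bt, Hbb-bs, Ms4a6d, Ccl9, Tmem109 and Irf8 fell in KO and rose in AT-3 cells, and Acot1, Slc6a12 and Tnfsf13b rose in KO and fell in AT-3 cells. The AT-3 call of Slc6a12 (-1.69) was lost with no filter (adjusted p = 0.0701), without wild-type array 1 (0.0898) and without wild-type array 2 (0.100), over a range of 0.00168 to 0.100. Its value was -2.46 without AT-3 array 1 and -1.03 without AT-3 array 2.

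Because the wild-type arrays are shared, chance values of both comparisons are shared as well. Across genes, the log2 changes correlated at 0.72 and had the same sign for 76.2%. Unchanged groups that shared a simulated control gave a median r of 0.50 (highest 0.53 of 100) and the same sign for 66.7%. At most 1 simulated gene was called in both. With nothing changed, few genes can be called at all, so that count does not test the overlap of groups that did change. Genes were simulated as independent, so the spread between real runs could be wider. The covariance was 0.863 against a simulated 0.0436, a difference of 0.819. With KO set against wild-type array 1 and AT-3 against wild-type array 2, r was 0.673 and the covariance 0.829, and with the controls exchanged they were 0.692 and 0.843. The controls cannot be split into parts of 2 arrays, so part of the excess over independent lists may come from the shared controls. The 2569 genes called in the same direction became 808 without wild-type array 1, 685 without wild-type array 2 and 1558 without AT-3 array 1. Of the 2569, 231 also differed between AT-3 and KO cells, and 91.0% did not pass that test.

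**Figure D4:**
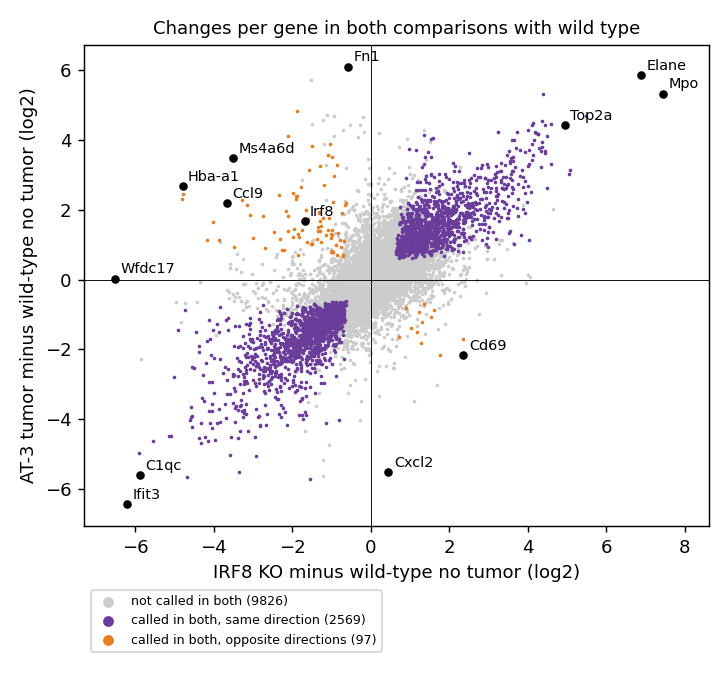
Log2 change of each gene in KO (horizontal axis) and AT-3 cells (vertical axis), both against wild type. Purple points are the 2569 genes called in the same direction and orange points the 97 called in opposite directions; Mpo and Elane lie at the upper right, C1qc and Ifit3 at the lower left, and Hba-a1 and Ms4a6d at the upper left.

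AT-3 cells were compared directly with KO cells to ask where both settings part. Hemoglobin and monocyte genes were higher in AT-3 cells. Hba-a1 was 177-fold higher (7.47, SE 0.28, adjusted p = 8.28e-05), with Hbb-bt at 152-fold and Hbb-bs at 140-fold. Hemoglobin genes have near-identical copies, as Hbb-bt and Hbb-bs are of each other, so which copy each probe reads is uncertain. Ms4a6d was 127-fold higher (6.98, SE 0.27), Ccl9 57.9-fold (5.86, SE 0.21), Ctsc 47.4-fold (5.57, SE 0.24), Stfa2 56.7-fold (5.83, SE 0.43) and Ccr2 at least 16.2-fold (4.49, SE 0.31). Fn1 was 103-fold higher (6.68, SE 0.48), by 7.29 without AT-3 array 2. Wfdc17 was 94.0-fold higher (6.55, SE 0.56), by 7.27 without KO array 1, 5.80 without KO array 2 and 7.24 without AT-3 array 1. Dusp2 was at least 13-fold lower (-4.16, SE 0.30), and Mogat2 fell by 4.05 (SE 0.32). Cxcl2 fell by 5.96 (SE 0.78), and was -7.09 and -4.87 without KO array 1 or 2 and -5.18 and -6.80 without AT-3 array 1 or 2. Tnfaip3, an inhibitor of NF-kappaB signaling, fell by 4.72 (SE 0.70), a call lost without AT-3 array 2 (-4.29, adjusted p = 0.0711, range 0.000726 to 0.0711).

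Of 22 monocyte and macrophage markers, 9 were higher, 1 lower and 12 did not pass (11 and 1 when adjusted over the list alone), with a median of 0.92 (camera adjusted p = 1.09e-05, and adjusted p = 0.903 with an estimated correlation). Of 17 erythroid markers, 9 were higher and 1 lower (12 and 1 when adjusted over the list alone), with a median of 1.82, or 1.38 with the bounds (camera adjusted p = 6.58e-07, and adjusted p = 0.903 with an estimated correlation). The erythroid median was 0.762 without AT-3 array 1. Of 25 receptor genes, 8 were higher and 1 lower (12 and 2 when adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.00022, and adjusted p = 0.903 with an estimated correlation). That median was -0.0263 with the median of all probes set equal and -0.125 with no scaling, where all genes shifted by -0.73 and -0.83. With the median of detected probes set equal the receptor call was lost (median 1.09, adjusted p = 0.161). Of 41 ribosomal protein genes, 4 were higher, also when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.000133, and adjusted p = 0.903 with an estimated correlation). Under the first 2 of those scalings it was -0.187 and -0.286 (adjusted p = 0.0469 and 0.0674), and without KO array 2 it was 0.242. Of 27 stress genes, 2 were higher and 11 lower (3 and 15 when adjusted over the list alone), with a median of -1.05 (camera adjusted p = 1.12e-05, and adjusted p = 0.903 with an estimated correlation). Of 14 B cell markers, 4 were lower (6 when adjusted over the list alone), with a median of -0.47, or -0.19 with the bounds (camera adjusted p = 0.00914, and adjusted p = 0.903 with an estimated correlation). The B cell call was lost without KO array 2 (median -0.315, adjusted p = 0.142, range 0.000477 to 0.903). Its median was -0.265 without wild-type array 1 and 0.268 with the median of detected probes set equal, where all genes shifted by 0.39 and the call was lost (adjusted p = 0.208). It was also lost with the median of all probes set equal (median -0.844, adjusted p = 0.389), with no scaling (-0.943, 0.349) and with detection under 0.01 on all arrays (-2.16, 0.137).

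With all arrays, cell cycle genes did not differ past the threshold between AT-3 and KO cells. Of 24 S phase and 22 G2/M genes, 0 passed in limma, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their camera adjusted p were 0.682 and 0.415, but each KO array alone gave a call, in opposite directions. Without KO array 1 the S phase and G2/M medians were 1.05 and 0.393 (camera adjusted p = 1.50e-08 and 0.0121), and without KO array 2 they were -0.925 and -0.742 (1.28e-07 and 2.93e-07). In both the IRF and STAT family and the MHC class II list, median and mean differed in sign. The former had 2 higher and 1 lower of 13, also when adjusted over the list alone, with a median of -0.14, a mean of 0.37 and an upward test (camera adjusted p = 0.603). Its Irf5 was 15.1-fold higher (3.91, SE 0.30), and Irf8, the targeted gene, was also among those higher. The latter had 5 higher and 2 lower of 16 (6 and 8 when adjusted over the list alone), with a median of -0.44 (-0.27 with the bounds), a mean of 0.29 and an upward test (camera adjusted p = 0.603). Ifi30 was 21.9-fold higher (4.46, SE 0.26) and Lgmn 7.72-fold higher (2.95, SE 0.24). Dendritic cell markers had 1 higher of 13, also when adjusted over the list alone, with a median of -0.06 (0.00 with the bounds), a mean of 0.04 and an upward test (camera adjusted p = 0.603).

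Of granule genes, Ctsc was higher and Serpinb1a, Cd63 and Olfm4 lower in AT-3 than in KO cells. The calls of Serpinb1a, Cd63 and Olfm4 were lost in 6 or 7 of 16 alternatives, with adjusted p up to 0.205. The primary granule list had 1 higher and 2 lower of 11 (1 and 2 when adjusted over the list alone), with a median of -1.03 (camera adjusted p = 0.505), and fry gave it the opposite direction. Without KO array 2 it passed camera (median -1.23, adjusted p = 2.96e-05), and without KO array 1 its median was 0.358. The secondary granule list had 1 lower of 15, and 0 in limma when adjusted over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.589). Mature neutrophil genes had 5 higher and 3 lower of 24 (7 and 3 when adjusted over the list alone, camera adjusted p = 0.285). That list passed without KO array 2 (adjusted p = 0.0211) or AT-3 array 1 (0.0423). Stfa2 and Stfa1 were higher, by 5.83 and 3.63. Granulopoiesis factors had 3 lower of 12 (3 when adjusted over the list alone, camera adjusted p = 0.312, but fry adjusted p = 0.00551), among them Cebpe (-2.02, SE 0.28), a call lost without KO array 2 (-1.50, adjusted p = 0.0530, range 0.000831 to 0.0530). NADPH oxidase genes had 1 lower of 6, Cybb (1 when adjusted over the list alone, camera adjusted p = 0.208). The Cybb call (-1.74) was lost in 5 of 15 alternatives, among them leaving out either wild-type array, KO array 2 or AT-3 array 2, with adjusted p up to 0.133. Suppressor genes had 1 higher, Wfdc17, and 3 lower of 21 (2 and 3 when adjusted over the list alone, camera adjusted p = 0.845).

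Interferon-stimulated genes had 1 higher and 2 lower of 35, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.589). That list passed without AT-3 array 1 (median 0.609, adjusted p = 0.000694). MHC class I genes had 1 higher and 1 lower of 14, also when adjusted over the list alone (camera adjusted p = 0.389). Described IRF8 targets had 2 higher and 1 lower of 21 (3 and 2 when adjusted over the list alone, camera adjusted p = 0.312). STAT3 and STAT5 targets had 2 higher and 1 lower of 22 (3 and 1 when adjusted over the list alone, camera adjusted p = 0.316), and Bcl3, a co-regulator of NF-kappaB, was higher (3.08, SE 0.34). Cytokines had 1 higher, Ccl9, and 3 lower of 22 (1 and 4 when adjusted over the list alone), with a median of -0.47, or -0.42 with the bounds (camera adjusted p = 0.316), and fry again gave the opposite direction. Without KO array 1 it passed (median -0.959, adjusted p = 0.0294). Glycolysis genes had 5 higher and 2 lower of 23, also when adjusted over the list alone (median 0.28, camera adjusted p = 0.0795, and 0.0122 without AT-3 array 1), and Mif was 6.62-fold higher (2.73, SE 0.32). None of 10 T cell markers passed in limma, also when adjusted over the list alone, and 5 had an unadjusted p under 0.05 (median -0.71, camera adjusted p = 0.0795, and 0.0294 without KO array 1 or 0.0423 without AT-3 array 1). None of 5 NK cell markers passed, 1 was lower when adjusted over the list alone and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.581). Megakaryocyte markers had 1 lower of 8, Gp9 (-1.67, SE 0.24), also when adjusted over the list alone, with a median of 0.01, a mean of -0.30 and a downward test (camera adjusted p = 0.505). None of 3 eosinophil markers passed, 1 was lower when adjusted over the list alone and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.589). None of 3 basophil markers passed, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.603). Progenitor genes had 1 higher, Spink2 (at least 4.11-fold), and 1 lower of 9 (2 and 2 when adjusted over the list alone, camera adjusted p = 0.913).

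In all, 1436 genes (11.5%) differed between AT-3 and KO cells, 769 higher and 667 lower, and 1219 by at least 2-fold. The arrays did not overlap for 54.6% of genes, against 33.3% by chance. The number called was 638 without wild-type array 1, 631 without wild-type array 2, 770 without AT-3 array 1 and 395 without AT-3 array 2. Of calls, 53.6% were higher with quantile scaling, 85.6% with the median of detected probes set equal, 5.79% with the median of all probes set equal and 4.81% with no scaling, where 4657, 6456 and 7085 genes were called. Over the 29 lists, camera with a preset correlation called 18 lists in KO, 13 in AT-3 and 6 between AT-3 and KO cells. With an estimated correlation camera called 0 in each, with 1, 1 and 0 lists at an unadjusted p under 0.05, and fry called 13, 15 and 2. Called by camera but not by fry were the primary granule, mature neutrophil, S phase, MHC class I, ribosomal, stress and T cell lists in KO cells, the S phase and MHC class II lists in AT-3 cells, and the receptor, ribosomal, stress, B cell and erythroid lists between AT-3 and KO cells. Fry tests movement of a list in 1 direction without setting it against other genes.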

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

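Among the tests in this part, those of array brightness, of a purer sort, and of B cells were chosen only after the results were seen, and those of erythroid cells, of fewer macrophages and of monocytic cells before.

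Genes called in opposite directions in KO and AT-3 cells were picked out because the difference between both effects passed its own test, which equals the direct comparison of AT-3 with KO cells. The AT-3 effect minus the KO effect was 3.36 on the log2 scale for Irf8 (KO -1.69, AT-3 1.67), 6.98 for Ms4a6d (KO -3.50, AT-3 3.48) and 4.76 for Tmem109 (KO -2.33, AT-3 2.43). It was 7.47 for Hba-a1, an alpha-globin gene. It was 7.25 for Hbb-bt and 7.12 for Hbb-bs, beta-globin genes that are near-identical copies of each other and so count as 1 signal. It was -4.53 for Cd69 (KO 2.36, AT-3 -2.17), -3.91 for Acot1 (KO 1.75, AT-3 -2.16), -4.03 for Slc6a12 (KO 2.35, AT-3 -1.69), -3.10 for Tnfsf13b (KO 1.29, AT-3 -1.81) and -2.52 for Fcrla (KO 1.31, AT-3 -1.20). Besides Irf8, treated below, calls of 3 of these depended on the setting. Fcrla lost its KO call in 9 of 15 alternatives (adjusted p up to 0.209; 0.772 without KO array 2), its AT-3 call in 10 (up to 0.395) and its direct call without AT-3 array 2 (0.0627). Cd69 lost its AT-3 call in 7 of 16 (up to 0.0889) and its KO call with no filter or without either wild-type array (up to 0.0710; 1.52 without KO array 2). Slc6a12 lost its AT-3 call with no filter or without either wild-type array (up to 0.100; -1.03 without AT-3 array 2). Each of the 2 arrays of a group showed its group's direction in all of these.

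Erythroid transcripts were higher in AT-3 than in wild-type cells: 11 of 17 listed erythroid genes rose and 6 did not pass, with Hba-a1 near 12.2 in wild-type, 7.4 in KO and 14.9 in AT-3 cells on the log2 scale. The dimmer AT-3 arrays and their normalization do not account for this, since the lowest median change of the list over the main and 6 other scalings was still 0.963. Without AT-3 array 1 the median was 0.861, against 1.76 with all arrays. With detection under 0.01 on all arrays the list's call was lost (camera adjusted p = 0.0552), though its median was still 1.76. Erythroid cells or their RNA among the sorted cells stay open, although the gate was CD11b+Gr-1high with a stated purity above 97%. Of 10 measured genes from a list of 17 further erythroid genes, 5 rose, among them Alad (4.30-fold) and Gypc (4.79-fold), and 0 fell in limma (0 at an unadjusted p under 0.05), while more than 5 had been required beforehand. A source in erythroid cells and a change within the sorted cells therefore cannot be told apart, and the tumor itself, the biological difference in the design, was not tested apart from them.

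Macrophage transcripts were lower in both KO and AT-3 than in wild-type cells, and brightness does not account for it: over all scalings and both comparisons the highest median change of the 10 tissue macrophage markers was -2.01. A purer sort would leave fewer cells of every other type. In KO cells the 12 B and T cell markers detected on both wild-type arrays had a median of -0.171. Of these, 4 rose and 0 fell in limma (0 lower at an unadjusted p under 0.05). These values argue against a purer sort there for B and T cells only, and the bounds were written after the results were seen. In AT-3 cells the same markers had a median of -0.601, 0 rose (1 at an unadjusted p under 0.05) and 2 fell, so a purer sort cannot be told apart there. Fewer macrophages among the sorted cells is consistent with a separate list of 13 macrophage genes, of which 8 of 9 measured fell in both comparisons and 0 rose, with 0 at an unadjusted p under 0.05 (Apoe 20.6-fold and 3.77-fold lower, Slc40a1 and Nr1h3 also lower), while a first version of the test on markers already seen had given 10 of 10. The gate is CD11b+Gr-1high at a stated purity above 97%, several of these genes can be expressed by monocytes within it, and loss of their expression in such cells would look alike, so this stays a hypothesis.

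Irf8 was higher in AT-3 than in wild-type cells, and the size of the rise depended on scaling: the lowest log2 difference over the main and 6 other scalings was 0.874 (SE 0.33, adjusted p = 0.0626, range over its alternatives 0.00513 to 0.0626), against 1.67 (SE 0.31) in the main setting. The call ended because the difference shrank at a like SE. The written bound on its size was met under every scaling. A call under each scaling was a further condition that the written bound did not hold, and it failed with no scaling. With no scaling the median of all genes was -0.44. Array brightness and a rise therefore cannot be told apart for part of the change. Monocytic cells among the CD11b+Gr-1high sorted cells, which the gate includes where Gr-1 is high, may add to it, but 16 measured of 20 further inflammatory monocyte genes had a median of -0.00300, with 5 up (Vcan at least 5.56-fold, S100a4 3.86-fold) and 5 down. A bound set beforehand, at or below 0, was met by far less than the spread of these genes, so this source and a change within granulocytes cannot be told apart. Of the 22 monocyte and macrophage markers in the main lists, 6 rose in AT-3 cells, among them Fn1, F13a1, Ccr2 and Ms4a6d, and 12 fell. In KO cells the Irf8 call was lost in 3 of 15 alternatives, 2 of which, no background correction and the authors' values, are the same data. In AT-3 cells it was lost in 2 (adjusted p up to 0.0626). B cells express Irf8 and should have been removed by the gate. Of 14 B cell markers, 0 rose in limma (0 at an unadjusted p under 0.05) and 1 fell. Their median was -0.45, or -0.08 with the bounds. These values argue against B cells as the source, but the condition was written after the results were seen.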

How the results depend on the processing

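The alternatives that set the median of all probes equal or left arrays unscaled were added after the data were seen. All others were planned. Per array, 31.0% to 38.4% of probes were detected. Of 256 calls on named genes, 235 kept direction and threshold without background correction, 246 with normexp alone, 246 with the median of detected probes set equal, 238 with the median of all probes, 236 with no scaling, 213 with no filter, 245 with averaged probes and 155 of 157 with the strict filter. Of 37 called lists, 37 kept theirs with normexp, 37 with no filter, 36 with averaged probes, 35 without background correction, 34 with the median of detected probes, 33 with the median of all probes, 31 with no scaling, 28 with the strict filter and 23 with fry. Unless the setting itself shows the cause, as fewer arrays or a stricter threshold do, the cause was not tested.

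Without background correction, and with the authors' log2 values, Irf8 in KO cells was at -0.635 (adjusted p = 0.0511). With no scaling, Irf8 in AT-3 cells was at 0.874 (adjusted p = 0.0626). Between AT-3 and KO cells, 4657 genes were called with the median of detected probes set equal, 6456 with that of all probes, 7085 with no scaling and 607 with only the arrays compared in the fit, against 1436. At an adjusted p under 0.01, 1964, 2080 and 411 genes were called in KO against wild type, AT-3 against wild type and AT-3 against KO. Camera with an estimated correlation called 0 lists in each comparison, and fry called 2 between AT-3 and KO cells, against 6.

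Some medians turned sign with scaling, where the median of all genes moved as well. Between AT-3 and KO cells, the B cell list was at 0.268 with the median of detected probes, the receptor list at -0.0263 and the ribosomal list at -0.187 with the median of all probes, and these at -0.125 and -0.286 with no scaling. With no scaling, AT-3 minus wild type was -0.00817 for the ribosomal list and -0.00603 for Hspa8. Nme7 between AT-3 and KO cells turned from -3.99 to 0.634 with the strict filter and to 0.733 and 0.496 without KO array 1 or 2, where another probe was the brightest. Leaving out each array gave -4.11 to 0.733.

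Leaving out each array in turn gave 1402 to 4282 genes in KO against wild type, 1377 to 5164 in AT-3 against wild type and 395 to 1726 in AT-3 against KO. It gave 685 to 3147 genes called in the same direction in KO and AT-3 cells, and 13 to 18, 13 to 15 and 6 to 10 lists. Without wild-type array 1 the gene counts were 1561, 1576, 638 and 808, without wild-type array 2 they were 1402, 1377, 631 and 685, and without AT-3 array 1 the last 3 were 2451, 770 and 1558. Without AT-3 array 2, 395 genes were called between AT-3 and KO cells, and 10 lists without KO array 1 or AT-3 array 1. Of the 1561 and 1402 genes in KO cells, 1543 and 1396 were also called with all arrays, and of the 1576 and 1377 in AT-3 cells, 1557 and 1375. Irf8 ranged from -1.87 to -1.39 in KO cells, from 1.33 to 2.06 in AT-3 cells and from 3.08 to 3.81 between them, with calls lost without wild-type array 1 (-1.60) and wild-type array 2 (1.57).

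The replicate numbers showed no visible pairing: replicate deviations correlated at 0.0859 (wild type and KO), -0.0552 (wild type and AT-3) and 0.00740 (KO and AT-3). Whether the numbers mark the experiments is not known. With the replicate block, 3750, 4154 and 1279 genes and 2444 shared ones were called, 251 of 256 named calls were kept and all 37 lists were.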

Other observations

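All tests of gene families in this part were chosen after the data were seen; the levels of single probes are given as values.

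Genes of the mitochondrial ribosome rose in AT-3 cells. Of 44 large subunit (Mrpl) genes, 26 rose and the others did not pass, with a median of 0.94 (camera adjusted p = 5.89e-06 over 230 families of at least 6 genes), and of 27 small subunit (Mrps) genes 15 rose, with a median of 0.99 (adjusted p = 0.00046). With an estimated correlation both had an adjusted p of 0.872. Both medians stayed positive under every scaling run, from 0.11 to 0.95 and from 0.17 to 1.00, where all genes shifted by up to 0.40 or down to -0.44. The Ndufa family of the respiratory chain's complex I had 8 of 13 genes higher with a median of 0.99 (adjusted p = 0.00692), which turned to -0.000486 with the median of all probes set equal and to -0.0560 with no scaling. With an estimated correlation the adjusted p of Ndufa was also 0.872. In KO cells, 9 of 27 Mrps genes rose and 1 fell (median 0.42, adjusted p = 0.0367) and 6 of 13 Ndufa genes rose (median 0.71, adjusted p = 0.0265), while 15 of 44 Mrpl genes rose and 3 fell (median 0.44, adjusted p = 0.0545). With an estimated correlation the adjusted p of all 3 in KO cells was 0.989.

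The medians of the H2bc and H2ac histone genes had opposite signs in both comparisons under every scaling run, though no test set the 2 types against each other. Of 12 H2bc genes, 8 fell and 1 rose in KO cells (median -2.07, adjusted p = 0.0306) and likewise in AT-3 cells (median -1.97, adjusted p = 0.0322), but with an estimated correlation the adjusted p was 0.989 and 0.872. Of 15 H2ac genes, 11 rose and 3 fell in KO cells (median 1.60, adjusted p = 0.0306, and 0.989 with an estimated correlation), and 8 rose and 3 fell in AT-3 cells (median 0.96, adjusted p = 0.177). H2ac6, H2ac18 and H2ac19 fell and H2bc21 rose in both comparisons. H2bc4 and H2bc14, picked like the other single histone genes after their values were seen, fell by 3.77 and 3.18 in KO cells, and H2ac15 rose by 3.23. Histone genes are close paralogs, so which copy each probe reads is uncertain.

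The rule of the brightest probe decided some neutrophil genes. For Ltf, the lactoferrin gene, the brightest probe read 25503 to 32541 over the 6 arrays, while another probe had raw signals of 982 and 1212 on the wild-type arrays, 10692 and 11714 on the KO arrays and 3542 and 3226 on the AT-3 arrays. For Lyz2, the lysozyme gene, the brightest probe read 25473 to 30885, while another had 4492 and 4312, 11732 and 11028, and 6236 and 5312.

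Single probes, picked after their values were seen, stood apart on single arrays. For Actb, 2 of 5 probes read 306.9 and 260.6 on wild-type array 1 but 20588 and 16145 on wild-type array 2, and 106.4 to 219.6 on the other arrays. A further Actb probe read 3918 on KO array 2 and 17175 to 32690 on the others. The KO arrays differed from each other more than the other pairs: 1121 of 12492 genes lay over 2-fold apart, against 132 in wild-type and 638 in AT-3 cells, with Elane (3.98 on the log2 scale), Prtn3 (3.87) and Mpo (3.28) among the widest.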
